A study of Arabidopsis thaliana with 7 samples.

How the data were processed

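The deposited table holds 1 value per transcript model and library, 23052 rows with 1 repeated row dropped, which leaves 23051 models of 21184 genes. The deposited signal values are counts that the authors scaled: each column is a whole multiple of 1 step (0.955, 0.961, 0.970 and 1 for Col-0 replicates 1 to 4, and 0.936, 0.921 and 0.963 for tt4-11 replicates 2 to 4), and the steps equal the inverse of DESeq2 median-of-ratios factors relative to Col-0 replicate 4. Dividing by the step gave back whole reads in 100% of values within a tolerance of 0.01. These sum to 2205449, 2099876, 2118112 and 2021368 reads in Col-0, and to 2151045, 2175787 and 2150718 in tt4-11. A count of 0 leaves room for up to 3 counts at this depth. Per the labels and the submitters' processing notes the reads were polyA-selected, stranded, 100-base single reads of a HiSeq 2500, handled with TopHat2, HISAT2, HTSeq and DESeq2. Versions and the genome build are not given in the sources used here.

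The test fixed before the data were examined was edgeR on counts, or limma if the table held no counts. Because 6 of 7 columns hold scaled values, limma was used as the main test and edgeR on the recovered reads as an alternative. Scaled values of all models of a gene were summed, 1 was added and the log2 taken. Genes were kept by filterByExpr (minimum count 10) on the scaled values, and limma with the trend option compared 3 tt4-11 with 4 Col-0 libraries with no other factor. A gene was called at a Benjamini-Hochberg adjusted p of 0.05, two-sided. Separately, 35 splits of the 7 libraries gave exact permutation p-values.

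The deposited log2 fold changes, their score (fold change over its error), the p-value columns and the other columns of ratios by the authors served for comparison only. They hold 1398 models at an adjusted p of 0.05 (731 higher and 667 lower in tt4-11), with TT4 at -4.94 (SE 0.15) by the authors' DESeq2. The deposited adjusted p is exactly 1 in 11177 rows, 1 further deposited log2 column of the authors, a ratio of group sums, differs from the ratio of means by an offset of 0.415, and 1015 cells hold spreadsheet errors. The name columns of 235 rows name a gene other than the row's identifier, so genes were matched by locus identifier alone, and 21154 were found in the TAIR10.1 annotation, which may not be the authors' build. That annotation supplied positions, symbols, lengths and GC content. Rows of the chloroplast and mitochondrial genomes are absent from the table, so their share of reads was not analysed here.

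Genes with several annotated models hold fewer reads in the table: the median scaled level is 37.9 with 1 model, 14.2 with 2, 7.81 with 3 and 5.02 with 4 or more. ACT2, normally abundant, stands at 0.832 and RCA at 24.4, against 7857 for LHCB1.3 and 11928 for PYK10. Levels of genes with several models are therefore not absolute levels, and counts were also made in the genes with 1 model (8416 tested, 1284 of the called genes) beside those with more (4745 tested, 521 called).

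Principal components of the log2 values put 44.7% of the variance on a first axis that separates the groups and 14.5% on a second, on which Col-0 replicate 1 stands at 26.1 and the other libraries between -23.3 and 13.5. No 2 libraries were duplicates (chi-square per degree of freedom 2.05 to 5.44 within groups, 5.67 to 13.6 between them). The labels name 4 tt4-11 libraries in the extraction text, of which replicates 2 to 4 are used here. The sample labels gave the grouping.

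The genes named in the report follow a rule fixed before the data were examined: TT4, called members of the 2 flavonoid lists, the 10 largest rises and falls among called genes with an average log2 CPM of at least 1 and fully separated groups, up to 4 called members of each further list with the lowest p (2 where none was called), and called neighbours of TT4. Values of some other members are given where a list splits in direction. The 27 lists (497 entries, 474 in the table) were also fixed before the data were examined. Lists with at least 5 tested members were tested with camera (preset correlation 0.01, two-sided, Benjamini-Hochberg over the lists), and again with an estimated correlation and with fry. Windows of 25 tested genes and the 10 tested genes on each side of TT4 were tested as given in the report.

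Alternatives fixed before the data were examined were DESeq2 and limma-voom on reads, upper-quartile factors, no filter, a filter of at least 10 counts in every library of 1 group, a pseudocount of 0.1, an adjusted p of 0.01, a change of at least 1 on the log2 scale, each library left out in turn, windows of 50 genes and shifted windows, the flavonoid list without TT4, and the authors' table. Added after seeing the data were edgeR on recovered reads, TMM factors, models as deposited, only genes with 1 annotated model, and removal of a trend of change with transcript length, alone or with GC content. Also added were 30 gene families by annotated product (at least 10 tested genes each), 1 list of genes known to respond rapidly to touch or wounding, and morning and evening sets of clock genes. Families were tested by 60 one-sided hypergeometric tests with Benjamini-Hochberg adjustment, and 10000 random lists of genes of matched level served as a comparison for the spread of a list between libraries. DESeq2 gave no adjusted p for AT3G16990, AT4G27654, AT5G62360, CBF1, ERF109, FLA11, ORA47 and PIN4, which its filter removes.

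The workflow was tested on simulated data of 13105 genes with 200 changed genes: limma recovered 23.9%, 76.1% and 95.5% of genes changed 1.5-, 2- and 4-fold, with 2.26% false calls, and gave 0 calls with no change planted. A planted list was found (adjusted p = 4.24e-23 with camera) with 0 of 20 unchanged lists called, and a planted window too (adjusted p = 4.45e-08, hypergeometric test). The simulated genes were drawn independently of each other, so this does not show how often lists of correlated genes pass by chance. A planted length trend went from a rho of 0.380 to -0.008 when removed, a drop that the removal itself brings about. With that trend planted, 29 of 154 calls lay outside the 200 changed genes, against 4 of 128 after its removal. The 2.26% of false calls above therefore holds only without such a trend.

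Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.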

Results

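RNA sequencing measured polyadenylated transcripts in whole 5-day-old Arabidopsis seedlings of the wild type Col-0 and of tt4-11, a line the labels describe as a null mutant of chalcone synthase. Seedlings grew at 22 °C under continuous light of about 100 µE, on medium with 2% sucrose, conditions the series describes as promoting flavonoid production. The labels give 4 Col-0 libraries (replicates 1 to 4) and 3 tt4-11 libraries (replicates 2 to 4), which are the samples analysed here. The table holds values for 21184 genes, and the reads behind it number 2021368 to 2205449 a library. Mean reads were 2111201 ± 75562 (SD, n = 4) in Col-0 and 2159183 ± 14380 (SD, n = 3) in tt4-11 (exact two-sided permutation p = 0.343).

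The question was which transcripts differ between seedlings with and without chalcone synthase, the enzyme of the first committed step of flavonoid synthesis. Levels below are scaled reads, Col-0 first (mean ± SD, n = 4) and tt4-11 second (mean ± SD, n = 3). Changes are differences of log2(value + 1) with their standard error (SE), a scale that understates the change of genes with few reads. Unless stated otherwise, adjusted p-values come from limma with Benjamini-Hochberg adjustment over the 13301 genes tested, and all gene tests were two-sided. The p-values measure only the spread between these samples, because the labels do not say whether the replicates were separate cultures. With 4 and 3 libraries the smallest exact two-sided permutation p possible was 0.0571, from 35 splits.

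TT4, the gene of chalcone synthase, lies on chromosome 5 of the TAIR10.1 build at 4488476 to 4490264 (plus strand, 2 exons, 4488476 to 4488954 and 4489041 to 4490264). Its scaled reads were 3003, 2571, 3148 and 2464 in Col-0 replicates 1 to 4, and 58.0, 96.7 and 54.9 in tt4-11 replicates 2 to 4. The means were 2797 ± 330 (SD, n = 4) and 69.9 ± 23.3 (SD, n = 3), so tt4-11 kept 2.50% of the Col-0 level. On the log2 scale TT4 fell by 5.34 (SE 0.16, 40.6-fold; limma with Benjamini-Hochberg adjustment, adjusted p = 2.99e-12), and the exact two-sided permutation p was 0.0571. The reads that remained in tt4-11 were 62, 105 and 57 (95% Poisson intervals, for counting error alone, 47.5 to 79.5, 85.9 to 127 and 43.2 to 73.9).

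**Figure D1:**
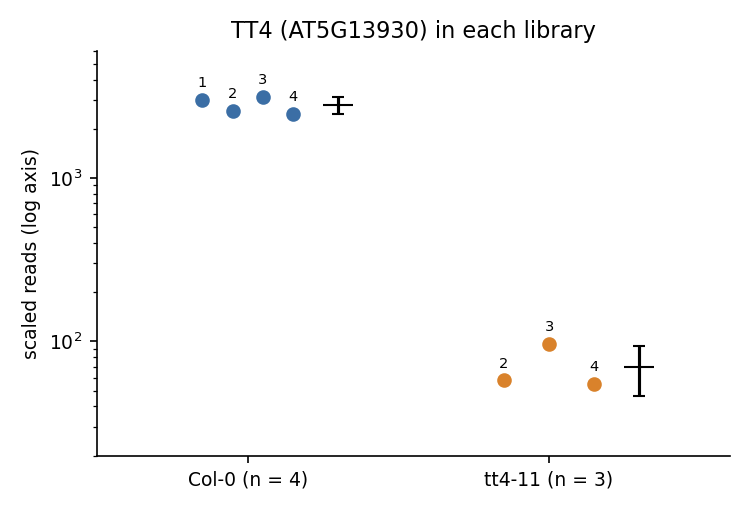
Scaled reads of TT4 (vertical axis, log scale) in each of the 4 Col-0 and 3 tt4-11 libraries (points), with the mean ± SD of each group (bars). The means were 2797 and 69.9.

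With TT4 included, 940 genes rose and 871 fell in tt4-11, with limma and Benjamini-Hochberg adjustment at an adjusted p of 0.05, which is 1811 or 13.6% of 13301 tested. The median size of a called change was 0.65 on the log2 scale, and 234 genes rose and 114 fell at least 2-fold. Every tt4-11 library lay beyond every Col-0 library in 3542 genes (26.6%), where chance alone gives 5.71%, and 1720 of the called genes were among them. The count dropped to 1135, 933 and 896 without tt4-11 replicates 2, 3 and 4, and was at least 1459 without any 1 Col-0 library. Long transcripts tended to be higher and short ones lower in tt4-11 (Spearman's rho = 0.288 over 13292 genes), and 1350 genes changed with that trend removed. Genes that share reads with near-identical paralogs, such as LHCB1 and LHCB2 members, the SESA genes, CBF1 with CBF2, and the RBCS genes, are uncertain as single genes.

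**Figure D2:**
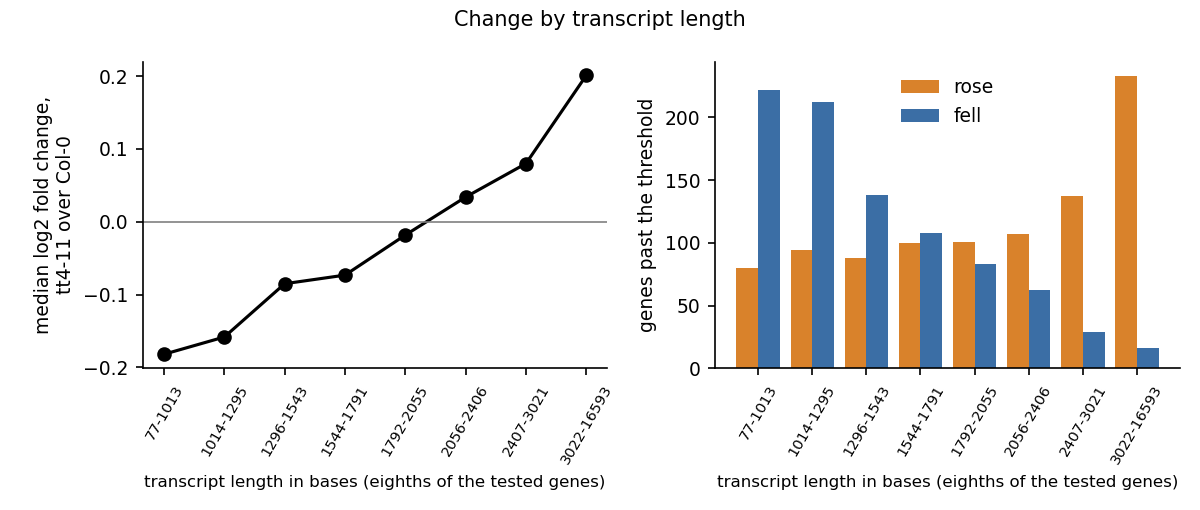
Median log2 fold change of tt4-11 over Col-0 in eighths of genes by transcript length (left, vertical axis) and the number of genes that rose or fell in each (right), from 80 and 222 in the shortest to 233 and 16 in the longest.

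The 10 largest rises included genes known to respond rapidly to cold or wounding. CBF2, a regulator of the cold response, rose from 10.2 ± 10 to 87.6 ± 19.2 (3.71, SE 0.71; adjusted p = 0.00303). ORA47, a jasmonate-related regulator induced by wounding, rose by 3.62 (SE 0.55, adjusted p = 0.000540; 3 reads in all Col-0 libraries and 59 in tt4-11, a ratio of 25.6 with a 95% interval of 8.36 to 128). ERF109, another wound-induced regulator, rose by 3.53 (SE 0.59, adjusted p = 0.00125; 2 reads against 46, a ratio of 30.0 with a 95% interval of 7.84 to 255). Both intervals pool the reads of a group and cover counting error alone, not the spread between libraries. HSPRO2, a defence gene, rose from 146 ± 96.2 to 945 ± 180 (2.90, SE 0.33; adjusted p = 3.23e-05). The Nudix hydrolases NUDT21 (55.3 ± 47.4 to 327 ± 11.1) and NUDT4 (51.7 ± 41.0 to 323 ± 16.4) rose by 3.08 (SE 0.53) and 3.06 (SE 0.47). AT4G29780 (44.9 ± 18.0 to 401 ± 41.8; 3.21, SE 0.23), AT5G17350 (3.21, SE 0.73), AT3G02840 (3.19, SE 0.34) and AT4G27654 (3.04, SE 0.66) made up the rest. All values are from limma with Benjamini-Hochberg adjustment, and AT5G17350 lost its call with DESeq2 (adjusted p = 0.119). Col-0 itself was uneven in these genes: CBF2 stood at 0, 23.1, 4.85 and 13 in replicates 1 to 4. Without Col-0 replicate 1 the changes of CBF2, AT5G17350, AT4G27654 and NUDT21 were 2.80, 2.26, 2.40 and 2.46, and without Col-0 replicate 2 those of CBF2 and AT5G17350 were 4.33 and 3.88. With the reads in edgeR ORA47 gave 4.46 and ERF109 4.59.

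The largest falls after TT4 included several genes with a daily rhythm. GRP7, a clock-controlled RNA-binding protein, fell from 312 ± 173 to 51.1 ± 15.2 (-2.49, SE 0.29; adjusted p = 5.32e-05), and its relative GRP8 by 2.21 (SE 0.40). FKF1, a blue-light receptor of the photoperiod pathway, fell from 61.1 ± 7.23 to 14.4 ± 4.35 (-2.04, SE 0.22; adjusted p = 2.36e-05). CCL, a transcript known for clock-dependent decay, fell from 545 ± 88.1 to 142 ± 13.8 (-1.92, SE 0.13; adjusted p = 3.63e-07). The arabinogalactan protein gene FLA11 fell by 2.05 (SE 0.42), AT5G62360 by 2.36 (SE 0.39), AT2G33830 by 2.19 (SE 0.31), AT5G23240 by 2.1 (SE 0.22) and AT3G16990 (-1.99, SE 0.47). All are from limma with Benjamini-Hochberg adjustment. Every tt4-11 library lay below every Col-0 library in each, which the rule for naming these genes required. AT3G16990 gave -1.23 without tt4-11 replicate 4.

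**Figure D3:**
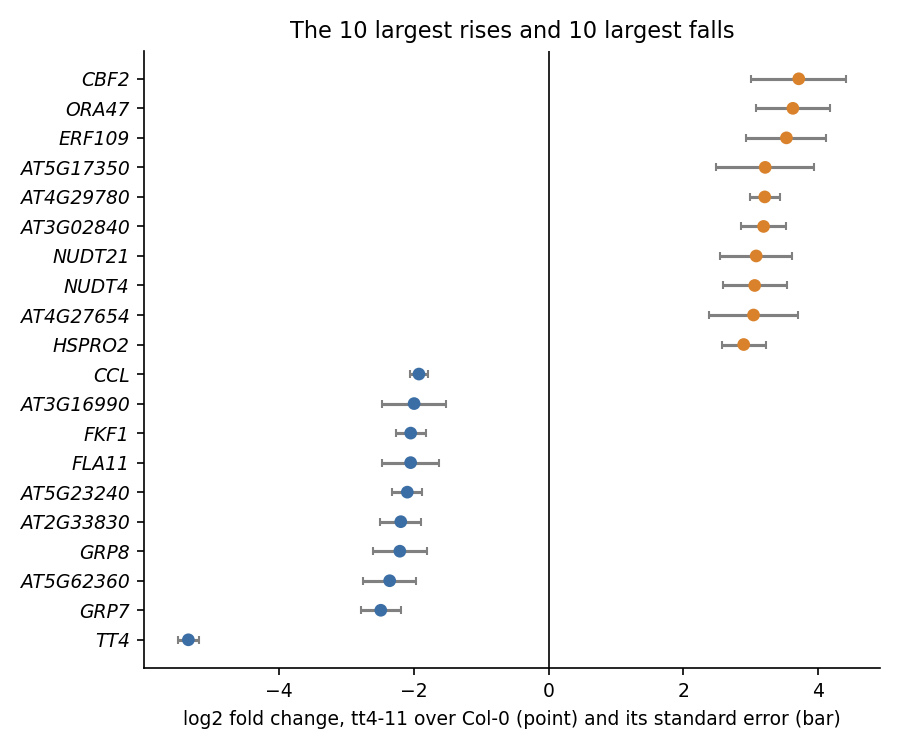
Log2 fold change of tt4-11 over Col-0 (horizontal axis) of the 10 genes with the largest rise and the 10 with the largest fall. Points are limma estimates and bars their standard errors, from 3.71 for CBF2 to -5.34 for TT4.

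In the flavonoid pathway 1 gene beside TT4 passed. Of 21 enzyme and transport genes tested, SCPL10, an acyltransferase that decorates anthocyanins, rose from 45.2 ± 19.4 to 101 ± 24.9 (1.23, SE 0.27; adjusted p = 0.00807), TT4 fell, and 19 did not pass. Adjusted over the list alone, 1 rose and 1 fell, and 7 were under 0.05 unadjusted. The next enzymes of the pathway gave -0.10 for TT5 (chalcone isomerase, 250 ± 17.5 and 234 ± 18.3), 0.21 for F3H, 0.41 for TT7, 0.16 for FLS1 and 0.12 for DFR, none of which passed (limma with Benjamini-Hochberg adjustment, adjusted p = 0.606, 0.601, 0.0564, 0.650 and 0.822). The list as a whole did not pass camera (adjusted p = 0.655; median 0.16, mean -0.04), nor without TT4 (adjusted p = 0.308, median 0.17). With DESeq2 on the reads, TT4 included, it passed downward (0.0290) although its median was 0.14 (main fit adjusted p = 0.862 with an estimated correlation). Among 10 regulators of the pathway, 0 rose and 0 fell with limma, 0 were under 0.05 unadjusted, 0 passed adjusted over the list alone, and DESeq2, edgeR and limma-voom each called 0. MYB12 (0.24), MYB111 (-0.20), TT8 (0.31) and HY5 (0.15), activators of the pathway, did not pass, nor did the list (camera adjusted p = 0.934; median -0.07, mean 0.00). The call of SCPL10 was lost without tt4-11 replicate 4 (adjusted p = 0.0529), and 3 enzyme and transport genes rose without Col-0 replicate 4.

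In the upstream and neighbouring phenylpropanoid, lignin and sinapate pathways 0 of 19 tested genes rose and 1 fell, also adjusted over the list alone. It was CAD4, an alcohol dehydrogenase of lignin synthesis (960 ± 119 to 706 ± 65.3; -0.44, SE 0.11; limma with Benjamini-Hochberg adjustment, adjusted p = 0.0169), whose call was lost without tt4-11 replicate 2 or 4 (adjusted p = 0.0749 and 0.0789). Without Col-0 replicate 4, 2 genes fell. The list did not pass camera (adjusted p = 0.388).

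Of 27 gene lists written before the data were examined, 23 had enough tested members for camera, and 3 passed: auxin response and seed markers upward, root hair genes downward. None of these 3 calls held with an estimated correlation between genes, where 0 lists passed. Without tt4-11 replicate 2 only 1 list passed, and without Col-0 replicate 1 or 3 there were 5. DESeq2, edgeR and limma-voom fits of the reads gave 9, 7 and 6 lists.

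**Figure D4:**
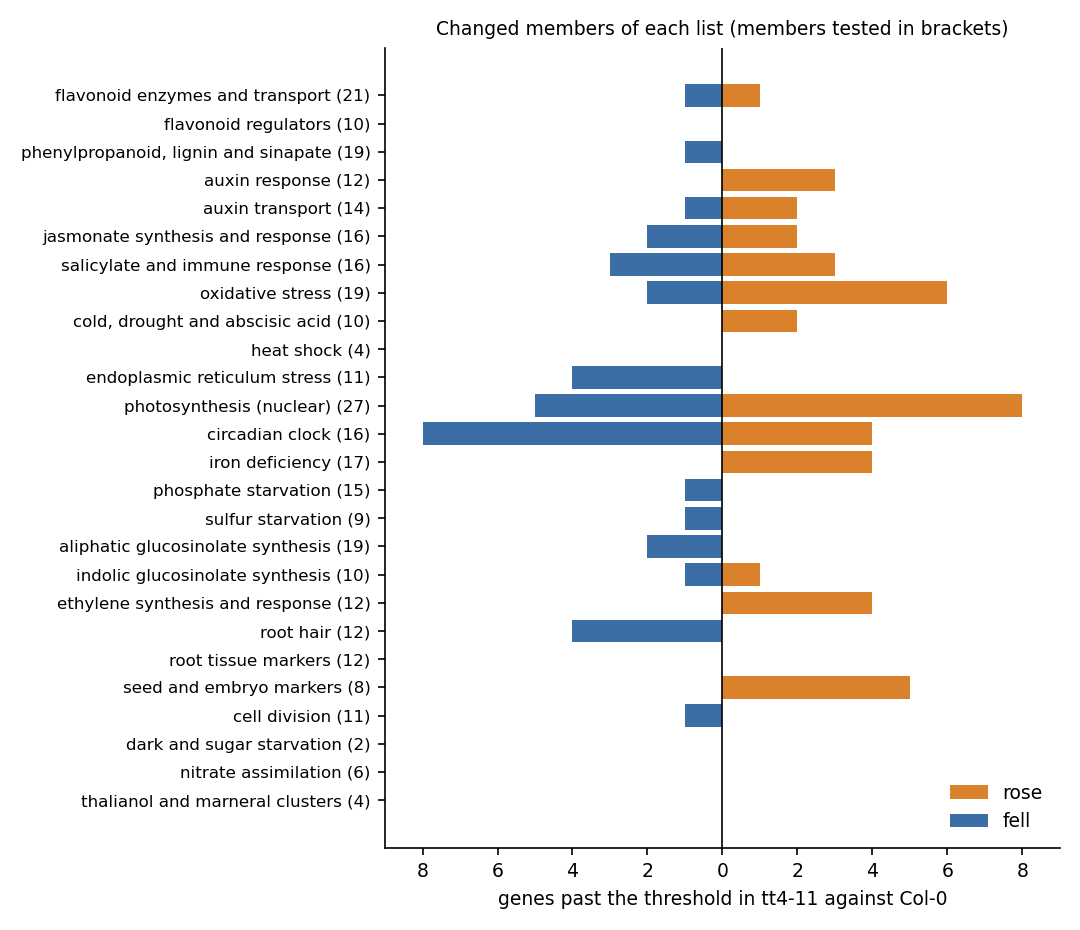
Number of genes of each of 26 lists that rose (bars to the right) or fell (bars to the left) in tt4-11 against Col-0. The number tested stands in brackets after each list name, and the circadian clock list had 4 rises and 8 falls.

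Of 12 auxin response genes tested 3 rose, 0 fell and 9 did not pass, with 4 rises adjusted over the list alone. HAT2, an auxin-induced homeobox gene, went from 52.6 ± 9.13 to 95.6 ± 4.27 (0.87, SE 0.17; adjusted p = 0.00358), IAA3, an auxin signalling repressor, from 78.7 ± 16.3 to 132 ± 7.24 (0.76, SE 0.16; adjusted p = 0.00642), and GH3.6, which conjugates auxin, from 435 ± 44.4 to 590 ± 70.6 (0.44, SE 0.11; adjusted p = 0.0185). In the list 11 of 12 members had positive values (median 0.40; camera adjusted p = 0.0128, and 0.0104 with fry), but camera gave an adjusted p = 0.491 with an estimated correlation. Of 14 auxin transport genes 2 rose, 1 fell and 11 did not pass (4 and 1 adjusted over the list alone): ABCB21 rose (0.56, SE 0.11, adjusted p = 0.00313), AUX1, an uptake carrier, rose (0.33, SE 0.10, adjusted p = 0.0460), and the efflux carrier PIN4 fell (-1.28, SE 0.35, adjusted p = 0.0227). That list did not pass camera (adjusted p = 0.653; median 0.06, mean -0.04). All gene values are from limma with Benjamini-Hochberg adjustment. The auxin response call was lost without tt4-11 replicate 2 (0.0779) and with no filter (0.114), GH3.6 without tt4-11 replicates 2 (0.0524) and 4 (0.114), and PIN4 without Col-0 replicate 3 (0.0692) and tt4-11 replicate 3 (0.114). AUX1 lost its call without any 1 library except Col-0 replicate 1 (adjusted p up to 0.216), and with the length trend removed (0.157).

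Clock genes split by phase. Of 16 tested 4 rose, 8 fell and 4 did not pass (5 and 10 adjusted over the list alone). CCA1, the morning regulator, rose from 38.2 ± 5.81 to 197 ± 10.8 (2.35, SE 0.16; adjusted p = 3.63e-07), with LNK2 (1.62), RVE1 (1.6) and RVE8 (1.23). Evening genes that fell, beside GRP7, GRP8 and FKF1, were ELF4 from 151 ± 16.9 to 63.1 ± 8.49 (-1.25, SE 0.15; adjusted p = 5.04e-05), GI (-1.16, SE 0.16; adjusted p = 0.000268), BOA (-1.1), PRR5 (-0.84) and TOC1 (-0.51). PRR7 (-0.48, adjusted p = 0.0595) and ELF3 (-0.36) did not pass. The list did not pass camera (limma with Benjamini-Hochberg adjustment, median -0.50, adjusted p = 0.116; 0.491 with an estimated correlation), but passed with fry (0.00724) and in genes with 1 annotated model (0.01). The 4 rising genes all have several annotated models, so in genes with 1 model 5 fell and 0 rose.

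**Figure D5:**
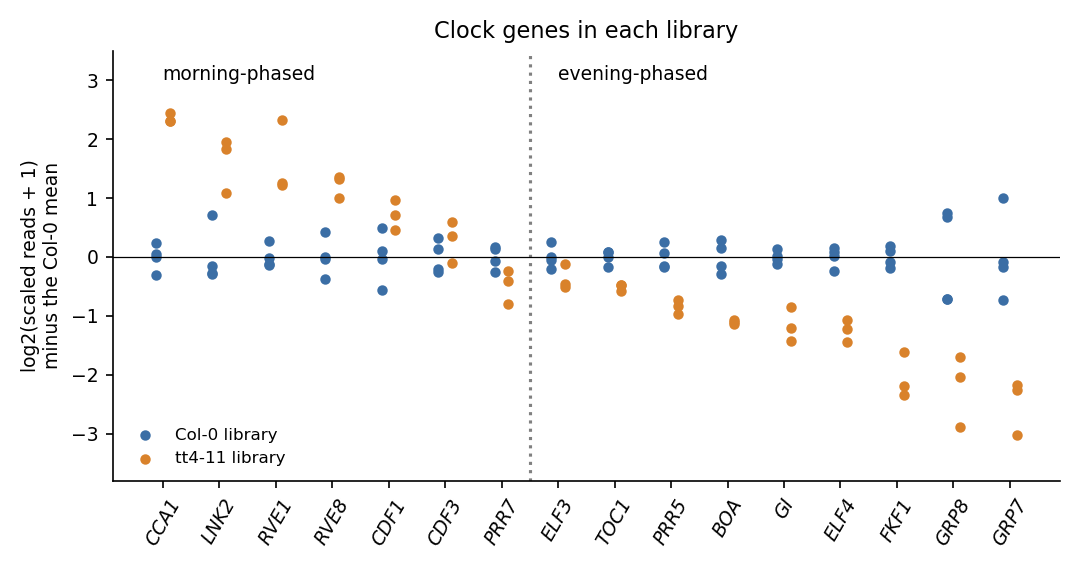
Level of each of 16 clock genes in each library as log2(scaled reads + 1) minus the Col-0 mean (vertical axis), morning genes beside evening genes. Each point is 1 of 7 libraries, coloured by group, and the tt4-11 points of CCA1 lie about its log2 change of 2.35.

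Nuclear photosynthesis genes moved in both directions: 8 of 27 tested rose, 5 fell and 14 did not pass (11 and 7 adjusted over the list alone). Among those that rose were the antenna protein genes LHCB3, from 818 ± 165 to 2060 ± 272 (1.34, SE 0.14; adjusted p = 1.80e-05), LHCB2.1, from 802 ± 152 to 1923 ± 256 (1.27, SE 0.13; adjusted p = 1.85e-05), LHCB1.1 (1.46, SE 0.18) and LHCB2.2 (0.84, SE 0.12). Those that fell were the photosystem I genes PSAF (-0.74) and PSAD1 (-0.40), PSBO1 of the oxygen-evolving complex (-0.47), the antenna protein gene LHCB4.1 (-0.46) and RBCS2B of Rubisco (-0.35). LHCB1.3, the most abundant of these, gave -0.23 (adjusted p = 0.205). The list did not pass camera (limma with Benjamini-Hochberg adjustment, median 0.14, adjusted p = 0.118). With the trend of change with transcript length removed 11 rose and 2 fell and the list passed upward (0.0121), with GC content also removed 14 rose and 1 fell (0.00044), and without tt4-11 replicate 3 only 1 fell (0.0241). Without Col-0 replicates 2 and 3 only 3 and 2 fell, and the list passed on the reads with DESeq2 (0.0290) and edgeR (0.0129), but in the main fit adjusted p = 0.796 with an estimated correlation.

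Ethylene genes: 4 of 12 tested rose, 0 fell and 8 did not pass, the same adjusted over the list alone. ACS6, a stress-induced enzyme of ethylene synthesis, rose from 44.8 ± 16.4 to 281 ± 14.9 (2.69, SE 0.22; adjusted p = 1.69e-06), ERF4, a transcriptional repressor, from 194 ± 24.5 to 425 ± 27.6 (1.13, SE 0.12; adjusted p = 1.80e-05), EBF2 by 0.35 (SE 0.10, adjusted p = 0.0291) and ACS7 by 1.1 (SE 0.32, adjusted p = 0.0298). The list did not pass camera (limma with Benjamini-Hochberg adjustment, median 0.13, adjusted p = 0.0874), but passed with fry (0.00758), in genes with 1 annotated model (0.00747), without Col-0 replicate 1 (0.0324) and on the reads with DESeq2 (0.000416), edgeR (0.000892) and limma-voom (0.0165). In the main fit it had adjusted p = 0.491 with an estimated correlation. Without Col-0 replicate 3 or tt4-11 replicate 3 or 4 only 2 genes rose. Calls of EBF2 and ACS7 were lost without single libraries (adjusted p up to 0.140 and 0.15, without tt4-11 replicate 4), and EBF2 also with the length trend removed (0.133).

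In the salicylate and immune list 3 of 16 tested rose, 3 fell and 10 did not pass (3 and 3 adjusted over the list alone; camera adjusted p = 0.172, but 0.0171 upward with DESeq2 and 0.0293 in genes with 1 annotated model; adjusted p = 0.796 with an estimated correlation). The regulators WRKY33 (70.2 ± 6.13 to 213 ± 64.1; 1.55, SE 0.17, adjusted p = 2.70e-05), WRKY46 (2.04, SE 0.27, adjusted p = 0.000174) and WRKY53 (1.31, SE 0.29, adjusted p = 0.00817) rose, while PR2, a glucanase and late marker of salicylate signalling, fell from 44.0 ± 9.66 to 19.4 ± 3.17 (-1.13, SE 0.23; adjusted p = 0.00477), as did PR1 (-2.41, adjusted p = 0.0236) and PR5 (-0.96, adjusted p = 0.0491). Only 1 of these 3 falls was called without Col-0 replicate 1, 3 or 4 or tt4-11 replicate 2 or 3, or with DESeq2 or limma-voom on the reads. In the jasmonate list 2 of 16 rose, 2 fell and 12 did not pass (2 and 2 adjusted over the list alone; camera adjusted p = 0.708). The allene oxide cyclase gene AOC2 fell from 474 ± 34.0 to 229 ± 67.0 (-1.08, SE 0.15; adjusted p = 0.000304) and AOC4 by 0.60 (SE 0.14, adjusted p = 0.0109), while AOC3 (0.65, SE 0.18, adjusted p = 0.0273) and MYC2, the central regulator, rose (0.81, SE 0.15, adjusted p = 0.00294). All are from limma with Benjamini-Hochberg adjustment. Without tt4-11 replicate 3 AOC3 (0.187) and AOC4 (0.0753) lost their calls, AOC3 also without Col-0 replicates 2 (0.0586) and 3 (0.0516) and with length and GC trends removed (0.0783), and WRKY53 lost its call without tt4-11 replicate 4 (0.0622). The change of AOC3 was 0.39 without tt4-11 replicate 3 and 0.81 without tt4-11 replicate 4.

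In the oxidative stress list 6 of 19 tested rose, 2 fell and 11 did not pass (7 and 2 adjusted over the list alone; camera adjusted p = 0.569, upward, with a median of -0.09 and a mean of 0.37). ZAT12, an early stress zinc finger, rose from 21.9 ± 10.7 to 77.0 ± 3.58 (1.91, SE 0.32; adjusted p = 0.00123), its relative ZAT10 by 2.1, and the catalase CAT2 by 1.26 (SE 0.25, adjusted p = 0.00379), while CAT1 fell from 139 ± 13.6 to 81.7 ± 9.29 (-0.76, SE 0.14; adjusted p = 0.00220) and FSD1 by 1.03. Only 1 of the 2 falls was called without Col-0 replicate 1 or tt4-11 replicate 3 or 4. In the cold, drought and abscisic acid list 2 of 10 rose, CBF2 and CBF1 (2.62, SE 0.67, adjusted p = 0.0171), 0 fell and 8 did not pass (3 and 1 adjusted over the list alone; camera adjusted p = 0.845, upward, with a median of -0.09 and a mean of 0.58). CBF1 gave 2.00 without Col-0 replicate 1 and 3.29 without Col-0 replicate 2, and lost its call without any 1 tt4-11 library (adjusted p up to 0.0754, limma with Benjamini-Hochberg adjustment). Of 4 heat shock genes, too few for camera, 0 passed with limma, 0 were under 0.05 unadjusted, 0 passed adjusted over the list alone, and DESeq2, edgeR and limma-voom called 0. HSP90.1 gave 0.21 (adjusted p = 0.242) and HSP23.5 -0.39 (adjusted p = 0.280), with HSP23.5 at -0.15 without Col-0 replicate 1 and -0.60 without Col-0 replicate 2.

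Genes of protein folding in the endoplasmic reticulum: 4 of 11 tested fell, 0 rose and 7 did not pass (1 rise and 6 falls adjusted over the list alone; camera adjusted p = 0.116, median -0.36). The chaperone gene BIP2 fell from 163 ± 83.4 to 64.4 ± 10.8 (-1.22, SE 0.25; adjusted p = 0.00480), PDIL1-1 by 0.73 (SE 0.16, adjusted p = 0.00748), CRT2 by 0.50 (SE 0.14, adjusted p = 0.0253) and CNX1 by 0.47 (SE 0.15, adjusted p = 0.0455), all with limma and Benjamini-Hochberg adjustment. With 1 library left out, all 4 falls were smallest without Col-0 replicate 1, at -0.91, -0.58, -0.37 and -0.32. Without tt4-11 replicate 3 or 4 the falls were 2, as CRT2 (0.0861 and 0.130) and CNX1 (0.0675 and 0.210) lost their calls. CNX1 also lost its call without Col-0 replicates 1 (0.0644) and 3 (0.0812) and tt4-11 replicate 2 (0.0857), and with length and GC trends removed (0.0799). The list passed on the reads with DESeq2 (0.0290), edgeR (0.0341) and limma-voom (0.0366), but in the main fit adjusted p = 0.796 with an estimated correlation.

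Among nutrient lists, iron deficiency genes gave 4 rises, 0 falls and 13 that did not pass of 17 tested (6 and 1 adjusted over the list alone; camera adjusted p = 0.0874, median 0.32). BTS, a ubiquitin ligase that restrains iron uptake, rose from 2799 ± 519 to 5310 ± 525 (0.94, SE 0.13; adjusted p = 0.000268), and the regulators BHLH101 (0.85, SE 0.18, adjusted p = 0.00605), BHLH38 (0.58, SE 0.15, adjusted p = 0.0199) and BHLH100 (0.83, SE 0.23, adjusted p = 0.0275) rose. With 1 library left out BHLH101 gave 0.70 to 1.00, BHLH38 0.47 to 0.71 and BHLH100 0.67 to 1.02. The lowest values came without Col-0 replicate 1 or 2 and the highest without Col-0 replicate 3 or 4. Of 15 phosphate starvation genes 1 fell, GDPD1 (-0.71, SE 0.15, adjusted p = 0.00685), and 14 did not pass (camera adjusted p = 0.116). Of 9 sulfur starvation genes 1 fell, APR3 (-0.85, SE 0.22, adjusted p = 0.0183), and 8 did not pass (camera adjusted p = 0.655), with 0 rises in either list and the same counts adjusted over the list alone. Of 6 nitrate assimilation genes 0 passed with limma, 4 were under 0.05 unadjusted, 3 rose and 1 fell adjusted over the list alone, and DESeq2, edgeR and limma-voom called 1, 0 and 1 (camera adjusted p = 0.583). NIA2 gave 0.33 (adjusted p = 0.0579) and GLN2 0.34 (adjusted p = 0.0959). Gene values are from limma with Benjamini-Hochberg adjustment. APR3 lost its call without tt4-11 replicate 4 (0.0979), GDPD1 with length and GC trends removed (0.192), BHLH38 and BHLH100 without single libraries (adjusted p up to 0.0794 and 0.131), and NIA2 passed without Col-0 replicate 3 (0.0453) and with DESeq2 (0.0254) and limma-voom (0.0304). The iron list passed with DESeq2 (0.0290), edgeR (0.0245), limma-voom (0.0225), without Col-0 replicate 3 (0.0118) and with the length trend removed (0.0304), and the phosphate list without Col-0 replicates 1 (0.0255) and 3 (0.0123), while in the main fit adjusted p = 0.796 with an estimated correlation for both. Without Col-0 replicates 1 and 3, 2 and 4 phosphate genes fell, and 1 rose without Col-0 replicate 2 or 4. Only 2 iron genes rose without Col-0 replicate 2 or tt4-11 replicate 2 or 4, 1 fell without Col-0 replicate 2 or 4, and 2 nitrate genes rose without Col-0 replicate 3.

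In glucosinolate synthesis 2 of 19 aliphatic genes fell, IPMI2 (-0.48, SE 0.13, adjusted p = 0.0235) and MAM1 (-0.33, SE 0.10, adjusted p = 0.0371), 0 rose and 17 did not pass, the same adjusted over the list alone (camera adjusted p = 0.708). Of 10 indolic genes 1 rose, the regulator MYB51 (94.3 ± 20.1 to 174 ± 23.1; 0.89, SE 0.17, adjusted p = 0.00328), 1 fell, CYP81F4, which modifies indole glucosinolates (-0.63, SE 0.17, adjusted p = 0.0217), and 8 did not pass (1 and 2 adjusted over the list alone; camera adjusted p = 0.569). Of 4 genes of the thalianol and marneral clusters 0 passed with limma, 0 were under 0.05 unadjusted, 0 passed adjusted over the list alone, and DESeq2, edgeR and limma-voom called 0. Of these CYP705A12 gave -0.49 (adjusted p = 0.727) and THAD -0.06 (adjusted p = 0.913, limma with Benjamini-Hochberg adjustment), but 0.70 and 0.24 without tt4-11 replicate 3. IPMI2, MAM1 and CYP81F4 lost their calls without single libraries (adjusted p up to 0.0879, 0.114 and 0.0866), IPMI2 also with the length trend removed (0.0991), and MAM1 (0.0731) and CYP81F4 (0.0951) with length and GC trends removed.

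Of 12 root hair genes tested 4 fell, 0 rose and 8 did not pass (0 and 5 adjusted over the list alone). They were the cell wall genes PRP1 (86.1 ± 17.5 to 46.6 ± 5.40; -0.86, SE 0.18, adjusted p = 0.00599), AGP3 (-0.73, SE 0.18, adjusted p = 0.0124), LRX1 (-0.83, SE 0.22, adjusted p = 0.0192) and XTH14 (-0.69, SE 0.20, adjusted p = 0.0287). The list passed camera (median -0.59, adjusted p = 0.0134), but adjusted p = 0.491 with an estimated correlation. Of 12 other root tissue markers 0 passed with limma, 3 were under 0.05 unadjusted, 0 passed adjusted over the list alone, and DESeq2, edgeR and limma-voom called 0. The endodermal regulator SHR gave -0.55 (adjusted p = 0.104) and the vacuolar channel TIP2-3 -0.91 (adjusted p = 0.132), and the list did not pass camera (adjusted p = 0.116; adjusted p = 0.491 with an estimated correlation) but did with fry (0.0104). Without Col-0 replicate 4 or tt4-11 replicate 2, 1 root tissue gene fell. Gene values are from limma with Benjamini-Hochberg adjustment. The root hair call was lost without tt4-11 replicate 4 (0.0698), with fry (0.0538) and with length and GC trends removed (0.0632). With the length trend removed 2 root hair genes fell, as AGP3 (0.0548) and XTH14 (0.0850) lost their calls, and with GC content removed as well 1 did, as LRX1 (0.0501) also lost its call. The gene calls of AGP3 without tt4-11 replicate 2 (0.0542), of LRX1 without tt4-11 replicate 4 (0.107) and of XTH14 without Col-0 replicate 3 (0.0802) and tt4-11 replicate 4 (0.165) were lost too, SHR passed without Col-0 replicate 4 (0.0205), and TIP2-3 gave -0.60 without tt4-11 replicate 4. XTH14 gave -0.41 without tt4-11 replicate 4 and -0.85 without tt4-11 replicate 3.

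Of 8 seed and embryo genes tested 5 rose, 0 fell and 3 did not pass (7 and 0 adjusted over the list alone). OLEO2, an oil body protein, went from 15.0 ± 15.8 to 71.7 ± 45.7 (2.46, SE 0.66; adjusted p = 0.0217), the albumin SESA3 from 26.8 ± 22.5 to 117 ± 76.9 (2.17, SE 0.61; adjusted p = 0.0273), the globulin CRU2 from 61.3 ± 65.8 to 251 ± 192 (2.3, SE 0.67; adjusted p = 0.0314) and OLEO1 from 33.7 ± 26.7 to 121 ± 92.4 (1.74, SE 0.53; adjusted p = 0.0376), all with limma and Benjamini-Hochberg adjustment. The list passed camera (median 1.96, adjusted p = 0.0128), but adjusted p = 0.796 with an estimated correlation and 0.278 with fry. The libraries differed widely within both groups: mean list scores against the Col-0 mean were -0.49, 0.36, 1.35 and -1.22 in Col-0 replicates 1 to 4, and 2.62, 2.16 and 0.45 in tt4-11 replicates 2 to 4 (exact two-sided permutation p = 0.114). No seed gene passed without tt4-11 replicate 2 or 3 or with DESeq2, 3 did without Col-0 replicate 1, 1 without Col-0 replicate 4 and 7 without tt4-11 replicate 4. Without tt4-11 replicates 2 and 4 CRU2 gave 1.69 and 3.07 and OLEO1 1.14 and 2.48. OLEO2 ranged from 1.97 (without Col-0 replicate 1) to 3.22 and SESA3 from 1.58 (without Col-0 replicate 4) to 2.96, both highest without tt4-11 replicate 4. The list call was lost without Col-0 replicate 4 (0.0562) and tt4-11 replicate 2 (0.0779).

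The remaining lists showed little. Of 11 cell division genes 1 fell, PCNA1, a clamp of DNA replication (-0.58, SE 0.15, adjusted p = 0.0201), 0 rose and 10 did not pass, the same adjusted over the list alone (camera adjusted p = 0.743). PCNA1 lost its call without Col-0 replicate 3 (0.0531) and tt4-11 replicates 3 (0.0696) and 4 (0.0962), with DESeq2 (0.0550) and with the length trend removed (0.0765). Without Col-0 replicate 2, 1 cell division gene rose, and without Col-0 replicate 4, 2 fell. Of 2 dark and sugar starvation genes 0 passed with limma, 1 was under 0.05 unadjusted, 0 passed adjusted over the list alone, and DESeq2, edgeR and limma-voom called 0, with DIN4 at -0.40 (adjusted p = 0.122) and DIN11 at 0.31 (adjusted p = 0.494, limma with Benjamini-Hochberg adjustment). Without tt4-11 replicate 3 DIN4 gave -0.20 and DIN11 0.02, and DIN11 gave 0.49 without tt4-11 replicate 2. Of 9 trichome genes 8 were in the table and 0 had enough reads to be tested by any tool.

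Near TT4 on chromosome 5, 2 of the 20 nearest tested genes changed, a share below the 13.6% called among all tested genes. NACA3, of a complex that binds nascent proteins, fell from 276 ± 84.2 to 124 ± 3.99 (-1.1, SE 0.17; adjusted p = 0.000623, and 0.00013 adjusted over the 20 alone), and TBP1, a telomere-binding protein gene, rose from 41.3 ± 5.78 to 75.0 ± 8.53 (0.85, SE 0.17; adjusted p = 0.00498, and 0.0016 adjusted over the 20 alone), both with limma and Benjamini-Hochberg adjustment. Along all chromosomes 0 of 529 windows of 25 consecutive tested genes held an excess of changed genes (one-sided hypergeometric test, Benjamini-Hochberg adjusted, lowest adjusted p = 0.525; 21 windows under 0.05 unadjusted; 0 with the calls of DESeq2, edgeR and limma-voom).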

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

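The tests of chance by relabelling were fixed before the data were examined, while the tests of stress handling, clock phase and transcript length were chosen only after the result was seen. In 7 of 90 items examined (genes, list means and library totals), all 7 of them genes, 1 Col-0 library stood far from the other 3 by Dixon's test, where chance alone gives about 5%, or 1 in 20. In ERF109 Col-0 replicate 2 was highest at 1.92 scaled reads, with 0 in the others. In HAT2 replicate 4 was lowest at 39.0 (others 55.3 to 58.3), and in PIN4 replicate 3 was highest at 24.3 (others 16 to 16.3). In WRKY33 replicate 1 was lowest at 61.1 (others 72.0 to 74.0). In BIP2 replicate 1 was highest at 288 (others 114 to 128), in APR3 replicate 1 was highest at 163 (others 82.0 to 92.3), and in EBF2 replicate 2 was highest at 2188 (others 1813 to 1869).

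Only the real grouping gave as many changed genes, 1 of 35 splits of the libraries with 1811 genes, against at most 164 in any other. A share of 1 in 35 is the lowest this test can give, so chance is made less likely but is not excluded. In the number of gene lists past camera the real grouping did not stand out, and chance cannot be excluded for the lists that passed. Of 35 splits 18 gave at least the 3 lists found, and the highest other gave 7. That number can miss a list whose members move in opposite directions. The clock list, with 4 rises and 8 falls of 16 tested, did not enter it. For windows along the chromosomes all 35 splits gave 0.

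Rapidly induced genes stood out: of 35 tested genes known to respond within minutes to touch or wounding, 29 rose and 0 fell (limma with Benjamini-Hochberg adjustment), but 11 of the listed genes were already in fixed lists and the list was written after the largest rises were seen. Their mean score was -0.59, 0.46, -0.16 and 0.29 in Col-0 replicates 1 to 4 and 1.48, 1.6 and 1.63 in tt4-11 replicates 2 to 4. Uneven handling shortly before freezing is a candidate explanation: the score already varied within Col-0 with an SD of 0.473, against a median of 0.0577 and a 95th percentile of 0.111 in random lists, although random lists are not co-regulated. Col-0 replicate 1 alone is argued against, since 29 of 29 calls held without it. An effect of genotype cannot be told apart from handling of each group, because the difference between groups, 1.57 (exact two-sided permutation p = 0.0571), would be the same.

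Clock genes differed as a shift of phase would have them differ: 15 of 16 rhythmic members lay in the direction of their textbook phase, with 7 morning genes at a median of 1.23 and 9 evening genes at -1.16. The exception was PRR7, and genes of 1 oscillator are not independent of each other. All 4 called morning genes have several annotated models, and in clock genes with 1 model 5 fell and 0 rose. A hypothesis is an offset of clock phase between the groups, for which the morning minus evening score gave -0.27, -0.08, 0.14 and 0.21 in Col-0 and 2.27, 2.43 and 2.42 in tt4-11. The labels give no harvest hour, so harvest at another circadian time and an effect of genotype cannot be told apart with a difference of 2.38 between groups.

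Short transcripts were lower and long ones higher in tt4-11, from a median log2 change of -0.18 in the shortest eighth of genes (77 to 1013 bases, 80 rose and 222 fell) to 0.20 in the longest (3022 to 16593 bases, 233 rose and 16 fell). For each library, length was correlated with the deviation of a gene's level from its mean over all libraries. These correlations were -0.13, -0.14, -0.13 and -0.27 in Col-0 and 0.13, 0.24 and 0.22 in tt4-11. Deviations from a shared mean take opposite signs in groups that differ, so only the difference between groups is informative. The trend was not confined to the 6 most displaced gene families, since rho was 0.272 over the 12714 genes outside them, against 0.288. These families were ribosomal proteins, histones, tubulins, immune receptors, glycine- and proline-rich wall proteins and AP2/ERF regulators. They are so small a share of the 13292 genes that leaving them out could hardly have lowered rho much, so no more is concluded from it. RNA quality or library preparation cannot be told apart from genotype: the range of the length correlation within Col-0 was 0.395 of the difference between groups. The same correlations with GC content were 0.22, 0.05, 0.14 and -0.13 in Col-0 and -0.15, -0.11 and -0.11 in tt4-11. By GC content the Col-0 libraries thus differed widely, and Col-0 replicate 4 lay within the range of tt4-11. The trend as the whole cause of fewer reads from 295 ribosomal protein genes is argued against, since their mean change of -0.269 was still -0.127 with the trend removed. This covers only the trend fitted on length. With it removed, Spearman's rho of change with GC content was -0.234, against -0.161 before, so other effects of library preparation are not covered.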

How the results depend on the processing

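The edgeR, TMM, single-model, models-as-deposited and trend-removal tests were chosen only after the result was seen. TT4 kept its direction and call everywhere (-5.60 to -5.20 with 1 library left out, -5.0 with length and GC trends removed). Changed genes were 896 to 1782 with 1 library left out, 426 to 925 higher and 437 to 857 lower: 1135 (610 and 525) without tt4-11 replicate 2, 933 (496 and 437) without 3, 896 (426 and 470) without 4, and 1459 or more without a Col-0 library. An adjusted p of 0.01 left 708 (394 and 314), a change of at least 1 on the log2 scale 348 (234 and 114). DESeq2 called 1437 genes and kept 1400 of the 1709 main calls it gave a p for, edgeR 1871, limma-voom 1843, TMM factors 1807, upper-quartile factors 1819, no filter 1636, at least 10 counts 1900, pseudocount 0.1 1779, genes with 1 model 1360, and 1398 models in the authors' table. With the length trend removed 1350 changed (783 and 567, 64.2% of main calls kept), with GC too 1243 (739 and 504, 58.1%). The cause was not tested.

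Lists past the threshold were 9 with DESeq2, 7 with edgeR, 6 with limma-voom, 6 in genes with 1 model, 5 with the length trend removed, 0 with an estimated correlation, 4 with fry, and 1 to 5 with 1 library left out (5 without Col-0 replicate 1 or 3, 1 without tt4-11 replicate 2). Neighbours of TT4 called were 1 in genes with 1 model, since TBP1 has 2, and 2 to 3 with 1 library left out. Windows stayed at 0 (lowest adjusted p 0.175 with 50 genes, 0.524 shifted). With replicate number as a replicate block 1665 genes changed (81.2% of main calls kept) and 6 lists passed. Numbers gave no clear pairing of libraries: replicates 2 and 4 of tt4-11 correlated best with their own number, at 0.06, and 3 did not. Correlations this small cannot show whether a number marks a shared batch.

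Medians near 0 reversed sign: flavonoid regulators 0.0293 with edgeR and 0.0304 with the length trend removed, flavonoid enzymes -0.0126 with the replicate block, cold and abscisic acid 0.19 with no filter, oxidative stress 0.15 in genes with 1 model and 0.0451 with length and GC removed, auxin transport -0.0163 and aliphatic glucosinolates 0.0653 with length removed. With 1 library left out the ranges were -0.0329 to 0.23 (flavonoid enzymes), -0.14 to 0.00894 (regulators), -0.16 to 0.00185 (phenylpropanoid), -0.18 to 0.0276 (oxidative stress), -0.00622 to 0.17 (auxin transport), -0.16 to 0.0338 (cell division), -1.10 to 0.70 (CYP705A12) and -0.36 to 0.24 (THAD). The cause was not tested. Organelle shares, and median-of-ratios factors other than the deposited ones, were not run. Depth of 2021368 to 2205449 reads limits genes with few reads.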

Other observations

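The tests of families and of the spread of seed genes were chosen only after the result was seen. Of 30 gene families by annotated product, ribosomal protein genes held the excess of falls with the lowest p, 89 of 295 (30.2%, against 6.60% of all genes; one-sided hypergeometric test with Benjamini-Hochberg adjustment, adjusted p = 3.2e-34). By p, histone genes came next with 14 of 30 lower (46.7%, adjusted p = 2.9e-08), then glycine- and proline-rich wall protein genes (24 of 110, adjusted p = 2.33e-06), tubulins (8 of 20, 40%, adjusted p = 0.000216), peroxidases (13 of 66, adjusted p = 0.00276), lipid transfer and 2S albumin family proteins (10 of 55, adjusted p = 0.0192) and arabinogalactan proteins (7 of 36, adjusted p = 0.0381). With the length trend removed 33 ribosomal protein genes (unadjusted exact one-sided hypergeometric p = 4.56e-07) and 5 histone genes (unadjusted exact p = 0.00838) were lower. In genes with 1 model 11 of 81 wall protein genes were lower (unadjusted exact p = 0.0916).

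Immune receptor genes with TIR or nucleotide-binding domains, among them RPM1, RPP1, RPP13 and ADR1, held the excess of rises with the lowest p, 30 of 86 (34.9%, against 7.11% of all genes; one-sided hypergeometric test with Benjamini-Hochberg adjustment, adjusted p = 1.89e-12). With the length trend removed 10 were higher (unadjusted exact one-sided hypergeometric p = 0.0305), and with GC content removed as well 7 (unadjusted exact p = 0.206). AP2/ERF regulators were higher in 13 of 37 (35.1%, adjusted p = 9.4e-06), and in 14 with the length trend removed. They include CBF1, CBF2 and ORA47, and the family mean was uneven within Col-0 (-0.33, 0.22, -0.08 and 0.19 in replicates 1 to 4, against 0.58, 0.68 and 0.62 in tt4-11). B-box regulators (6 of 17, 35.3%, adjusted p = 0.00598), EF-hand calcium sensors (11 of 61, adjusted p = 0.0208) and WRKY regulators (7 of 31, adjusted p = 0.0261) were higher too. Light-harvesting and photosystem proteins went both ways, 10 of 55 higher (adjusted p = 0.0261) and 7 lower (12.7%, adjusted p = 0.229). Protein kinases did not pass (43 of 437 higher, adjusted p = 0.0798). These tests treat the genes of a family as independent.

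Seed genes varied together between libraries, with a mean pairwise correlation of 0.717 against a median of -0.015 and a 95th percentile of 0.166 in random lists. Random lists are not co-regulated, so a list of co-regulated genes would exceed them in any case.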
